A study of Mus musculus with 6 samples.

How the data were processed

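RNA was taken from microdissected dentate gyrus of mice on postnatal day 7, per the labels' protocols, with 3 control samples and 3 Jmjd3 null samples. Libraries were made from polyadenylated RNA with a stranded Illumina TruSeq mRNA kit, per the labels' protocols. The deposited table compares the genotypes gene by gene and has the columns of a Cuffdiff gene table. The tools named were TopHat2 version 2.0.10 and Cuffdiff version 2.1.1 with genome build mm9, per the submitters' processing notes. The gene annotation and the library normalization were not given in the sources used here.

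The deposited FPKM is 1 value per gene and genotype, per the file headers, in which replicates are already combined. The authors' log2 fold is the null over the control with no pseudocount, and it is infinite where a group is listed at 0. The deposited test statistic is a score with the sign of the fold. The deposited p-value and q-value are those of Cuffdiff per the submitters' processing notes and the file headers, and genes that were not tested carry a p of 1. The smallest p in the table is 5e-05, shared by 524 genes, which sets their q at 0.00136. Of 23307 genes listed, 14257 were tested and 9050 were not.

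No value per sample was used, since the table holds group values alone. The depth of each sample is therefore unknown, no SD can be given, and no interval from counts can be set. No count model, leave-one-out fit or test of other splits of the samples was run for the same reason. The planned design foresaw this case: the authors' q under 0.05 among tested genes is the main test, with no test of its own, and the p-values measure only what Cuffdiff took from the spread of these 6 samples. How many litters or animals stand behind each sample is not given in the sources used here.

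The deposited values were checked against each other. The deposited log2 fold matched the ratio of the FPKM values within 0.01 for 99.993% of tested genes with both groups above 0, and the largest gap was 0.0434. The deposited q equalled a Benjamini-Hochberg adjustment of the p-values over tested genes to within 5.23e-07. The deposited p was compared with the deposited statistic: over 12770 genes, the normal deviate of the p was a median of 1.73 times the statistic, with a 5th to 95th percentile range of 1.66 to 1.78, and the square root of the number of samples per group is 1.73. No header says how the p was made from the statistic, so calls from a normal p of the statistic are given beside the lists as well. That normal p leaves out the factor of 1.73, and it was larger than the deposited p for 14074 tested genes. It is an alternative reading and not the authors' test, so a gene that does not pass with it is still called at the deposited q. The ratio leaves out genes at the smallest deposited p, and single genes such as Prm1 lie far from it. Scaled by that factor, the statistic implies a standard error of the log2 fold with a median of 0.12 (quartiles 0.11 and 0.15), an inference from the values and not a deposited error. By expression, the median was 0.17 for genes of 1 to 5 FPKM, 0.12 for 5 to 20 FPKM and 0.10 for 20 to 100 FPKM. Among genes with an absolute log2 fold of 0.5 to 1, 63.2% were called in the lowest of these classes, 93.8% in the next and 97.8% in the third, so a lack of a call says less for genes of low expression.

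A total of 29 gene lists, the named genes rule and the alternatives were fixed before the data were examined. Members were measured where they were tested and had a mean of at least 1 FPKM, which 13300 genes did. A list's median log2 fold of FPKM with a pseudocount of 1 was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression, and stands apart below percentile 2.5 or above 97.5. A fold on this scale understates the change of low genes. Of 27 lists with at least 3 measured members, 11 stood apart, 6 above and 5 below. Fisher's exact test, 2-sided, compared list membership with calls in each direction among the 13300 genes, with Benjamini-Hochberg adjustment over 54 tests, of which 11 had an adjusted p under 0.05. Both describe this table across genes, which are not independent replicates. Some genes are on several lists, such as Calb2, Nhlh2, Id4 and Pdgfra. For each list the p-values were also adjusted over the list alone.

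The genes named were Kdm6b, Kdm6a and Ezh2, the 12 called genes with the largest fold in each direction with a mean of at least 1 FPKM and a finite fold, leaving out unnamed gene models, and from each list up to 4 called members by absolute fold or, where none was called, up to 3 of highest expression. A few of the genes this rule names, and 1 of the gene families tested, are not reported here. Coordinates are as the deposited table gives them, in mm9. The reference genome at hand was another build and was not used. Entries that share a locus with another gene can share reads, and 133 called genes shared a locus. Among them were Matn4, Bcas1, Gpr17, Xist, H19, Ebf3, Gabra3, Ppp1r1b and Fam26e, which are named below. Entries for short RNAs, such as microRNAs and small nucleolar RNAs, numbered 736 and held 79.4% of the summed control FPKM and 78.6% of the summed null FPKM, although 2 of them were called, so no share of the total FPKM was used.

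A calling step was run on simulated data, in which 200 of 13267 genes were changed and independent normal noise followed the implied standard errors. Its calls came from a normal p with those same errors, adjusted by the Benjamini-Hochberg method, and not from Cuffdiff. The rates therefore follow from that setting and do not test the calls of Cuffdiff. The errors rest on the factor of 1.73, and the reading without it, with larger errors, was not simulated. A change of 0.5 on the log2 scale was called in 67.2% of 67 genes, of 1 in 97.0% of 67 genes and of 2 in 100% of 66 genes, and 5.88% of the 187 called genes were unchanged ones. Of 100 unchanged lists of 20 genes, 8% fell outside the central 95%, and all of 100 lists shifted by 0.5 did. Those lists were random genes with independent noise, so the 8% does not cover lists of markers that move together. The alternatives were a q of 0.01 and of 0.1, an absolute log2 fold of at least 1, a mean of at least 1 FPKM, q recomputed over those genes, folds centred on the median, other pseudocounts, filters and random lists, and another background; alternatives added after seeing the data are named in the closing section. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.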

Results

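The dentate gyrus was microdissected from mice on postnatal day 7, and polyadenylated RNA was sequenced from 3 control and 3 Jmjd3 null samples, which the submitters call biological replicates. The null animals carried the hGFAP-Cre driver, a transgene that expresses Cre recombinase under the human GFAP promoter in radial glial progenitors, and Jmjd3 alleles whose JmjC catalytic domain is flanked by loxP sites. The controls were littermates. If they lacked the Cre transgene, any effect of the transgene itself is not separated from that of the deletion. Jmjd3, whose gene symbol is Kdm6b, is a demethylase that removes methyl groups from lysine 27 of histone H3, a mark of repressed genes. The comparison asks how gene expression in the early postnatal dentate gyrus, where the stem cells of adult neurogenesis are set aside, differs when this enzyme is deleted from the radial glial lineage. The values are the authors' FPKM, fragment counts scaled to transcript length and to mapped fragments, with 1 value per gene and genotype. The depth of each sample and the spread between samples are unknown, because the values were combined over replicates, so each call rests on the authors' own test.

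Kdm6b itself fell in the null, from 10.7 to 5.77 FPKM in the authors' deposited table, a log2 fold of -0.89 with a Cuffdiff q of 0.00136. The gene lies on chromosome 11 between 69212019 and 69227177 in the mm9 build used by the authors, and its gene-level value also covers exons outside the deleted part. Its relative Kdm6a, the X-linked H3K27 demethylase, was at 9.01 FPKM in the control and 7.83 FPKM in the null (q = 0.417), and Ezh2, the methyltransferase that writes the mark, was at 15.4 and 14.5 FPKM (q = 0.897) in the authors' deposited table. Among 26 measured genes of the H3K27 methylation machinery, Kdm6b was the single gene called at the deposited q, and it was also the single call when the q was adjusted over the list alone. The list's median log2 fold was -0.020, at percentile 34.1 of random lists matched on expression.

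Of 14257 genes tested, 1036 differed between the genotypes at a Cuffdiff q under 0.05 in the authors' deposited table, 552 of them higher and 484 lower in the null, and 2169 had an unadjusted p under 0.05. The called genes made up 7.27% of those tested. Most differences were moderate: the median absolute log2 fold of the called genes was 0.57, and 153 of them reached an absolute log2 fold of at least 1. The median log2 fold over the 13300 tested genes with a mean of at least 1 FPKM was -0.0062. The deposited p was below a normal p of the statistic printed beside it for 14074 tested genes and above it for 183, of which 108 were at the smallest p in the table. When the normal p-values were adjusted by the Benjamini-Hochberg method, 263 entries passed, 132 higher and 131 lower. Of these, 213 were among the 1036 called genes, Kdm6b included, and the other 50 were all short RNA entries not called at the deposited q.

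**Figure D1:**
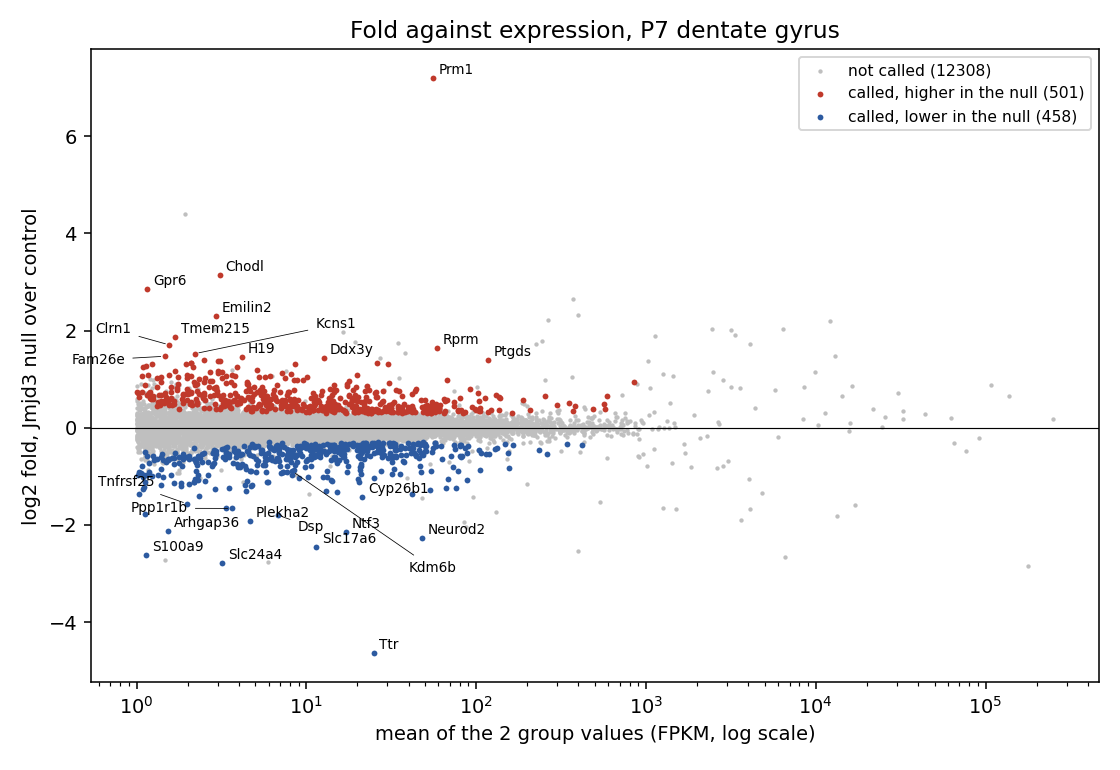
Log2 fold of the Jmjd3 null over the control (vertical axis) against the mean of the 2 group values in FPKM (log scale) for each tested gene of at least 1 FPKM with a finite fold; each point is a gene, red where called higher, blue where called lower and grey where not called. The labels mark Kdm6b and the 12 called genes with the largest fold in each direction, from Prm1 at 7.19 to Ttr at -4.64.

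The largest rise belonged to Prm1, a protamine that packages DNA in sperm, which went from 0.756 to 111 FPKM in the authors' deposited table (log2 fold 7.19, q = 0.0382); where in the gene its reads lie is unknown. It was followed in that ranking by Chodl, a membrane lectin, from 0.629 to 5.56 FPKM (log2 fold 3.14), and the orphan receptor Gpr6, from 0.279 to 2.03 FPKM (log2 fold 2.86, q = 0.0314), both in the authors' deposited table. Emilin2, an extracellular matrix glycoprotein, rose by a log2 fold of 2.30, Tmem215 by 1.87 and Clrn1 by 1.71 in the authors' deposited table. Rprm, whose product reprimo has been tied to cell cycle arrest, went from 28.4 to 88.7 FPKM (log2 fold 1.64) in the authors' deposited table. The potassium channel subunit Kcns1 rose by a log2 fold of 1.53, Fam26e by 1.47 and the imprinted noncoding RNA H19 by 1.45, per the authors' deposited table. The remaining genes of this set were the helicase Ddx3y (log2 fold 1.43), a Y-linked gene expressed in males alone, and Ptgds, the prostaglandin D synthase of the meninges and other brain barriers, which went from 64.1 to 169 FPKM (log2 fold 1.40) in the authors' deposited table. Of these 12 genes, Gpr6 and Fam26e did not pass with the normal p of the deposited statistic.

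The largest fall was that of Ttr, the thyroid hormone carrier made by choroid plexus epithelium, from 47.9 to 1.92 FPKM (log2 fold -4.64, q = 0.00136) in the authors' deposited table. The sodium-calcium exchanger Slc24a4 and the myeloid protein S100a9 followed with log2 folds of -2.78 and -2.62, the latter at 1.96 FPKM in the control (q = 0.0213 in the authors' deposited table). Slc17a6, the vesicular glutamate transporter VGLUT2, fell from 19.3 to 3.55 FPKM (log2 fold -2.45) in the authors' deposited table. Neurod2, a basic helix-loop-helix factor of differentiating excitatory neurons, fell from 79.2 to 16.4 FPKM (log2 fold -2.27), and the neurotrophin Ntf3 from 27.9 to 6.34 FPKM (log2 fold -2.14), in the authors' deposited table. Arhgap36, Plekha2, the desmosomal protein Dsp and Ppp1r1b, the phosphatase inhibitor DARPP-32, had log2 folds of -2.13, -1.92, -1.80 and -1.66 in the authors' deposited table. Tnfrsf25 and the retinoic acid hydroxylase Cyp26b1 completed the set at -1.56 and -1.43, with Cyp26b1 going from 31.1 to 11.5 FPKM in the authors' deposited table. Of these 12 genes, S100a9 did not pass with the normal p of the deposited statistic.

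Most genes of mature granule neurons, the principal cells of the dentate gyrus, were lower in the null. Their folds were below 0 for 22 members and above 0 for 4. Of 26 measured, 15 were called lower, none was called higher and 11 did not pass; adjusted over the list alone, 19 were lower. The set included Plekha2, Dsp, the lactase gene Lct (4.10 to 1.71 FPKM, log2 fold -1.26) and the cation channel Trpc6 (3.43 to 1.60 FPKM, log2 fold -1.10), all at q = 0.00136 in the authors' deposited table. Prox1, the transcription factor that specifies granule cell identity, was at 132 FPKM in the control and 114 FPKM in the null (log2 fold -0.21, q = 0.353) in the authors' deposited table; it is named here after its values were seen. The list's median log2 fold of FPKM + 1 was -0.57, lower than that of all 10000 matched random lists, whose central 95% ran from -0.07 to 0.06. Called-lower genes were over-represented in it (odds ratio 39.4, adjusted p = 2.76e-14, Fisher's exact test, 2-sided), and 12 of the 15, with Plekha2, Dsp, Lct and Trpc6 among them, also passed with calls from the deposited statistic. Meningeal fibroblast genes, with a median of 0.50, were higher in the same libraries.

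Genes of immature granule neurons moved in both directions. Of 19 measured, 7 rose, 5 fell and 7 did not pass; adjusted over the list alone, 9 rose and 6 fell. Gap43, a growth cone protein of extending axons, rose from 198 to 313 FPKM (log2 fold 0.66), while Neurod2, the tachykinin gene Tac2 (17.7 to 8.80 FPKM, log2 fold -1.01) and the transcription factor Bhlhe22 (201 to 112 FPKM, log2 fold -0.84) fell, each at q = 0.00136 in the authors' deposited table. The median log2 fold was 0.16, at percentile 99.99 of matched random lists. Both directions were over-represented, with an odds ratio of 15.1 for higher calls (adjusted p = 4.80e-05) and 10.1 for lower calls (adjusted p = 0.00201, Fisher's exact test). With calls taken from the deposited statistic, 2 of the 7 higher and 3 of the 5 lower genes passed, with the 4 examples above among them, and the enrichment of higher calls did not (odds ratio 12.6). In a permutation test across genes, which are not replicates, chosen after the calls were seen, the mature median lay below the immature median by -0.72 (p = 0.00208, adjusted over 3 contrasts 0.00208).

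Radial-glia-like stem cell genes showed few calls. Of 23 measured, 3 fell and 20 did not pass. Id4, an inhibitor of basic helix-loop-helix factors, went from 39.6 to 26.3 FPKM (log2 fold -0.59), the endothelin receptor Ednrb from 48.5 to 34.0 FPKM (log2 fold -0.51) and the matrix protein Tnc from 43.8 to 32.7 FPKM (log2 fold -0.42), each at q = 0.00136 in the authors' deposited table. The list's median log2 fold was 0.011, at percentile 70.0, and lower calls were not over-represented after adjustment (odds ratio 4.22, adjusted p = 0.180, Fisher's exact test). Among 14 intermediate progenitor genes, the RNA-binding protein gene Elavl2 rose from 34.6 to 46.0 FPKM (log2 fold 0.41, q = 0.00136) and Neurod4 fell from 3.39 to 2.37 FPKM (log2 fold -0.52, q = 0.0162) in the authors' deposited table. Adjusted over the list alone, 3 were higher and 1 lower, and the median of 0.076 stood at percentile 97.7, a position it lost under 4 other settings. With calls from the deposited statistic, no radial-glia-like or intermediate progenitor gene passed, so Id4, Ednrb, Tnc, Elavl2 and Neurod4 were called at the deposited q alone.

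None of 37 cell cycle genes was called by Cuffdiff, and 1 had an unadjusted p under 0.05. The replication clamp Pcna was at 61.4 FPKM in the control and 61.6 FPKM in the null, the helicase subunit Mcm7 at 22.9 and 22.5 FPKM, and the ribonucleotide reductase subunit Rrm1 at 15.6 and 15.1 FPKM in the authors' deposited table. Adjusted over the list alone, the count was also 0. The median log2 fold was -0.043, at percentile 13.9.

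Other neuron classes changed in part. Of 10 Cajal-Retzius cell genes, 5 fell and 2 rose, and 7 were lower adjusted over the list alone. The transcription factor genes Ebf3 (2.32 to 1.53 FPKM, log2 fold -0.61) and Nhlh2 (13.5 to 8.85 FPKM, log2 fold -0.60) and the secreted factor Ndnf (15.7 to 11.3 FPKM, log2 fold -0.48) fell, and Car10 rose from 4.52 to 9.80 FPKM (log2 fold 1.12) in the authors' deposited table. The list's median of -0.33 lay below all matched random lists, and lower calls were over-represented (odds ratio 28.3, adjusted p = 0.000113, Fisher's exact test), although with calls from the deposited statistic Car10 was the single member to pass. Nhlh2 is also on the immature granule list.

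Of 17 pyramidal neuron genes, 5 rose and 3 fell, and 5 and 4 did so adjusted over the list alone. The matricellular protein gene Nov (2.13 to 3.74 FPKM, log2 fold 0.81), the kainate receptor subunit Grik4 (21.2 to 35.7 FPKM, log2 fold 0.75) and Iyd (3.27 to 5.498 FPKM, log2 fold 0.75) rose, while the transcription factor Bcl11b fell from 33.5 to 16.3 FPKM (log2 fold -1.03), all at q = 0.00136 in the authors' deposited table. Higher calls were over-represented (odds ratio 10.7, adjusted p = 0.00191, Fisher's exact test), but not with calls from the deposited statistic (odds ratio 14.3), where Nov and Iyd did not pass and Grik4 and Bcl11b did. The median of 0.082 stood at percentile 98.4, and at 96.1 among genes of at least 5 FPKM, where it no longer stood apart. Among 18 interneuron genes, the neuropeptide gene Vip rose from 1.19 to 2.99 FPKM (log2 fold 1.33) and Cck, which is also made by other hippocampal neurons, fell from 42.0 to 21.8 FPKM (log2 fold -0.94), with the other 16 not called in the authors' deposited table; both also passed with calls from the deposited statistic. Adjusted over the list alone, 3 were higher and 1 lower, and the median of 0.13 stood at percentile 99.9, but among genes of at least 5 FPKM it was 0.057 at percentile 91.2 and no longer stood apart. Of 11 genes of the thalamus and other neighbouring regions, 3 fell and 1 rose, with 4 and 2 adjusted over the list alone: Slc17a6, the netrin-G gene Ntng1 (1.95 to 0.855 FPKM, log2 fold -1.19) and Zic1 (10.5 to 7.92 FPKM, log2 fold -0.41) fell and the calcium-binding protein Calb2 rose from 92.9 to 119 FPKM (log2 fold 0.35) in the authors' deposited table. The median of that list was -0.035, at percentile 24.8, and -0.17, at percentile 0.340, among genes of at least 5 FPKM. Lower calls were over-represented (odds ratio 10.6, adjusted p = 0.0269, Fisher's exact test), a result lost at a q of 0.01 and with calls from the deposited statistic, where Slc17a6 alone passed.

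Most called genes of the astrocyte and oligodendrocyte lineage lists were lower in the null, with Cldn11 called higher. Of 24 astrocyte genes, 8 fell and none rose, and adjusted over the list alone 10 were lower and 2 higher. The water channel Aqp4 went from 98.8 to 64.6 FPKM (log2 fold -0.61), the metallothioneins Mt2 from 136 to 93.3 FPKM (log2 fold -0.54) and Mt1 from 182 to 127 FPKM (log2 fold -0.51), and the link protein Hapln1 from 20.1 to 14.8 FPKM (log2 fold -0.44), each at q = 0.00136 in the authors' deposited table. The median of -0.19 lay below all matched random lists, with an odds ratio of 14.2 for lower calls (adjusted p = 1.54e-05, Fisher's exact test). With calls from the deposited statistic no astrocyte gene passed. Meningeal genes, with a median of 0.50, were higher in the libraries in which these glial genes were lower.

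All 14 oligodendrocyte precursor genes had folds below 0, and 5 of them were called lower, or 9 adjusted over the list alone. The sialidase Neu4 (1.91 to 0.941 FPKM, log2 fold -1.02), Matn4 (9.52 to 6.13 FPKM, log2 fold -0.64), Bcas1 (15.4 to 10.5 FPKM, log2 fold -0.55) and the receptor Gpr17 (23.1 to 16.9 FPKM, log2 fold -0.45) fell at q = 0.00136 in the authors' deposited table. The median of -0.27 lay below all matched random lists, and lower calls were over-represented (odds ratio 15.7, adjusted p = 0.000571, Fisher's exact test), though not with calls from the deposited statistic (odds ratio 8.03), where Neu4 alone passed. Of 11 myelinating oligodendrocyte genes, 5 fell and 1 rose, and 5 and 2 did so adjusted over the list alone. The myelin lipid enzyme Ugt8a (3.57 to 2.15 FPKM, log2 fold -0.73) and Enpp6 (1.60 to 1.03 FPKM, log2 fold -0.63, q = 0.0262) fell, whereas the tight junction gene Cldn11 rose from 3.23 to 4.97 FPKM (log2 fold 0.62, q = 0.00902) in the authors' deposited table. That median was -0.12, at percentile 1.36, and no longer stood apart with a smaller pseudocount or at 5 FPKM (percentile 2.98). Its odds ratio for lower calls was 23.6 (adjusted p = 0.000168, Fisher's exact test). The enrichment did not pass at a q of 0.01 (odds ratio 8.75), nor with calls from the deposited statistic, where no member passed in either direction.

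Markers of the meninges moved with genotype. Of 15 meningeal fibroblast genes, 9 rose, none fell and 6 did not pass, and 10 were higher adjusted over the list alone. Besides Ptgds these included the retinoic acid synthesis enzyme Aldh1a2 (3.33 to 5.89 FPKM, log2 fold 0.82) and the proteoglycans Lum (2.08 to 3.66 FPKM, log2 fold 0.81) and Dcn (10.05 to 17.5 FPKM, log2 fold 0.80), each at q = 0.00136 in the authors' deposited table. The median of 0.50 lay above all matched random lists, and higher calls were over-represented (odds ratio 38.9, adjusted p = 1.60e-08, Fisher's exact test). With calls from the deposited statistic, 3 of the 9 passed, Ptgds, Dcn and Col3a1, while Aldh1a2 and Lum did not. The oligodendrocyte precursor, astrocyte and mature granule lists were lower in the same libraries.

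No microglial gene was called by Cuffdiff among 17 measured, and 1 had an unadjusted p under 0.05. The complement gene C1qc was at 19.02 FPKM in the control and 19.9 FPKM in the null, and C1qa at 18.6 and 20.5 FPKM, in the authors' deposited table. The list's median was -0.030, at percentile 31.3. Among 17 endothelial genes Vwf rose from 1.11 to 1.51 FPKM (log2 fold 0.45, q = 0.0362), and among 10 pericyte and smooth muscle genes Vtn rose from 26.0 to 33.0 FPKM (log2 fold 0.35, q = 0.0276) in the authors' deposited table. Their medians were -0.0080, at percentile 53.2, and -0.050, at percentile 20.5. Adjusted over the list alone, 1 endothelial gene and 2 pericyte genes were higher; neither Vwf nor Vtn passed with calls from the deposited statistic. Of 6 measured genes of the choroid plexus and ependyma, Ttr fell under both readings of the p and the other 5 did not pass, with a median of -0.10 at percentile 8.29. Of the blood genes, Alas2 was the single one measured, at 1.83 FPKM in the control and 2.09 FPKM in the null (q = 0.822) in the authors' deposited table.

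**Figure D2:**
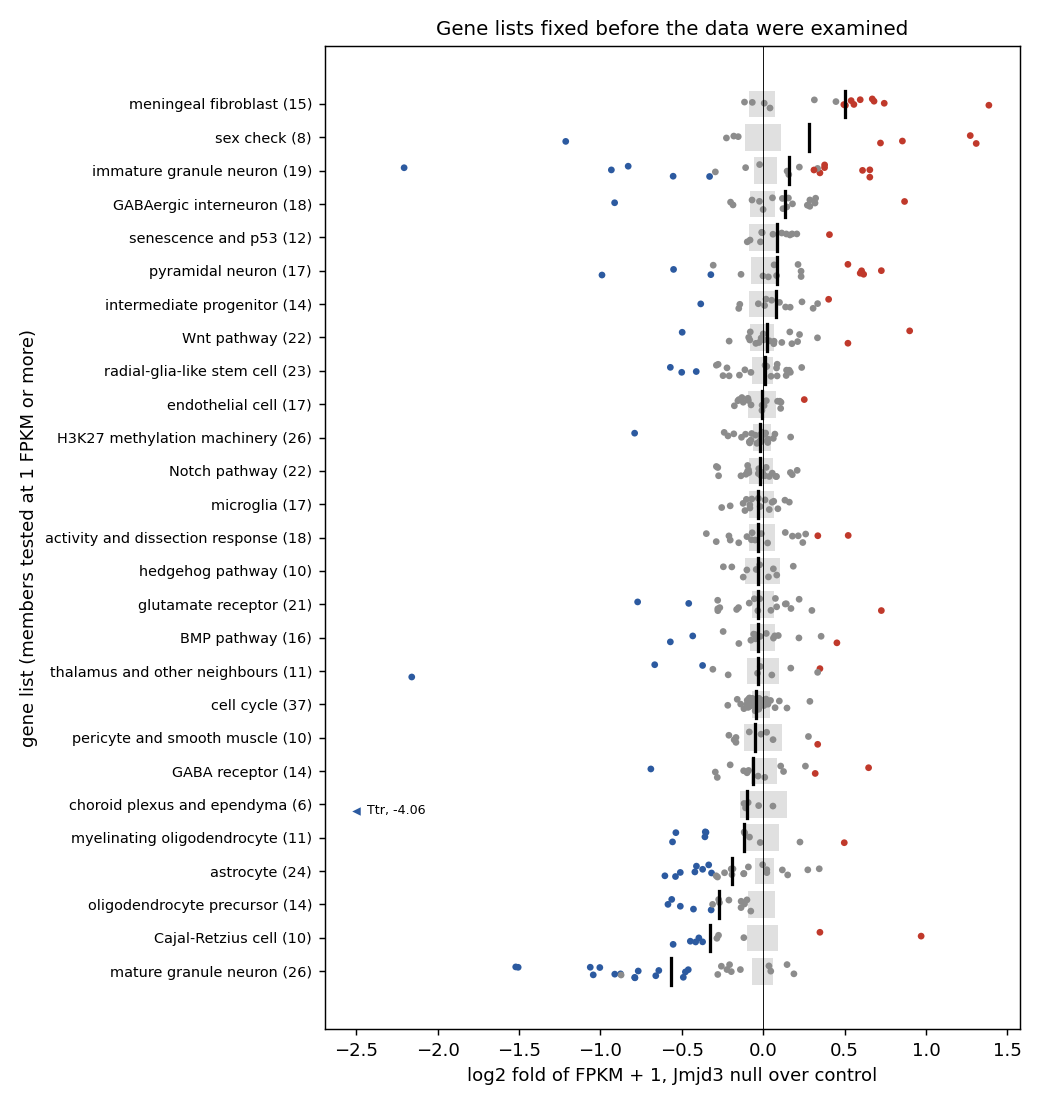
Log2 fold of FPKM + 1, Jmjd3 null over control (horizontal axis), for the members of 27 gene lists (vertical axis, number measured in brackets); points are genes, red where called higher, blue where called lower and grey where not called, black bars are list medians, and grey bands hold the central 95% of medians of 10000 random lists matched on expression. The medians of mature granule neuron genes (-0.57) and meningeal fibroblast genes (0.50) stand farthest from 0, and Ttr lies beyond the left edge, drawn there with its value of -4.06.

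Signalling pathways that act on dentate stem cells showed isolated calls. None of 22 Notch pathway genes and none of 10 hedgehog pathway genes was called by Cuffdiff; unadjusted p-values under 0.05 were found for 2 Notch genes and 1 hedgehog gene. In the authors' deposited table, the Notch target Hes5 was at 20.9 FPKM in the control and 23.6 FPKM in the null, Hey1 at 19.97 and 18.7 FPKM, and Rfng at 33.9 and 31.6 FPKM, while Gas1, Smo and Sufu of the hedgehog pathway were at 15.1 against 14.6, 10.7 against 12.3 and 9.45 against 9.68 FPKM. The medians were -0.021 at percentile 43.0 for Notch and -0.033 at percentile 33.2 for hedgehog. Of 22 Wnt pathway genes, the Wnt agonist Rspo2 (3.95 to 8.24 FPKM, log2 fold 1.06) and the receptor Fzd7 (1.45 to 2.52 FPKM, log2 fold 0.79) rose, and Rspo3, a paralogue of Rspo2, fell from 3.03 to 1.86 FPKM (log2 fold -0.71, q = 0.00554) in the authors' deposited table. Of 16 BMP pathway genes, Bmp5 rose from 0.790 to 1.45 FPKM (log2 fold 0.88), and Id4 and Id2 (149 to 110 FPKM, log2 fold -0.44) fell in the authors' deposited table. Adjusted over the list alone, 3 Wnt genes were higher and 1 lower, and 2 BMP genes were higher and 2 lower. Their medians of 0.020 and -0.033 stood at percentiles 79.6 and 23.1. Rspo2 also passed with calls from the deposited statistic, and Fzd7, Rspo3, Bmp5, Id4 and Id2 did not. Of 39 Hox genes, classic targets of H3K27 methylation, none was tested, and the highest value was 0.0426 FPKM in the control and 0.159 FPKM in the null.

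Neurotransmitter receptors changed in a few subunits. Of 21 glutamate receptor genes, the metabotropic receptor Grm2 (26.2 to 14.9 FPKM, log2 fold -0.81) and the NMDA receptor subunit Grin2c (2.09 to 1.25 FPKM, log2 fold -0.74) fell and Grik4 rose in the authors' deposited table; adjusted over the list alone, 6 were lower and 2 higher. Of 14 GABA receptor genes, Gabrd, the delta subunit of extrasynaptic receptors, fell from 5.65 to 3.12 FPKM (log2 fold -0.86), and Gabra3 (3.93 to 6.72 FPKM, log2 fold 0.77) and Gabra2 (76.9 to 96.1 FPKM, log2 fold 0.32, q = 0.0206) rose in the authors' deposited table; adjusted over the list alone, 3 were lower and 2 higher. The medians were -0.033 at percentile 17.6 and -0.061 at percentile 5.34. Of 18 genes that respond to activity or dissection, Nr4a3 rose from 26.7 to 38.8 FPKM (log2 fold 0.54) and Npas4 from 1.35 to 1.97 FPKM (log2 fold 0.54, q = 0.0308) in the authors' deposited table, and the median was -0.031 at percentile 27.6, with 2 genes higher and 1 lower adjusted over the list alone. Of 12 senescence and p53 pathway genes, the cell cycle inhibitor Cdkn1a rose from 8.24 to 11.3 FPKM (log2 fold 0.45, q = 0.00554 in the authors' deposited table), the single call also when adjusted over the list alone, with a median of 0.087 at percentile 97.3, and at 98.3 with no filter on low values, where it stood apart. Grm2, Grik4 and Gabra3 also passed with calls from the deposited statistic, and Grin2c, Gabrd, Gabra2, Nr4a3, Npas4 and Cdkn1a did not.

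Sex-linked genes differed between the pooled groups, and the labels used here give no sex of the animals. Genotype and sex are therefore not separated for these genes, Ddx3y included. All 4 measured Y-linked genes were called higher in the null, with a median log2 fold of FPKM + 1 of 1.06. With the X-linked Xist, given below, called lower, these values point to a larger share of male RNA in the null group. Genotype and sex are therefore not separated for any other call either, autosomal genes included. Xist, the RNA of the inactive X chromosome, was lower in the null, at 39.6 against 93.2 FPKM (log2 fold -1.23, q = 0.00455), while the Y-linked Ddx3y (6.90 to 18.6 FPKM), Eif2s3y (14.9 to 37.5 FPKM) and Uty (1.85 to 4.16 FPKM) were higher, each at q = 0.00136 in the authors' deposited table. Of 8 measured genes of this check, 4 were called higher and 1 lower, and 4 and 2 were so adjusted over the list alone; the list median of 0.28 stood at percentile 100 and became -0.17 among genes of at least 5 FPKM. Higher calls were over-represented in it (odds ratio 25.7, adjusted p = 0.000840, Fisher's exact test). Ddx3y, Eif2s3y and Uty also passed with calls from the deposited statistic, and Xist did not. On the X chromosome 19 of 473 tested genes of at least 1 FPKM were called higher and 16 lower. Without genes of either sex chromosome, 995 genes were called, a count that does not remove any effect of sex on autosomal genes.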

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

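Some entries that Cuffdiff listed but did not test reached 1 FPKM, in the control as well as in the null. Of the untested entries in the authors' deposited table, 81 had at least 1 FPKM in either group, and all 81 were short RNA entries such as microRNAs and small nucleolar RNAs. Of these, 40 were higher in the null than in the control, 28 of them listed at 0 in the control, and 41 were lower, with 39 listed at 0 in the null. The difference was not tested.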

How the results depend on the processing

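The alternatives named without further remark were fixed before the data were examined. Those without shared loci, short RNA entries, sex chromosomes or neighbouring-tissue genes, and the p from the deposited statistic, were chosen after seeing the data. The count of 1036 called genes ranged from 721 at a q of 0.01 to 1329 at a q of 0.1, and was 961 with a mean of at least 1 FPKM, with or without a new adjustment. Without shared loci it was 903, without short RNA entries 1034, without chromosomes X and Y 995 and without meningeal, choroid plexus and blood genes 1025. Centring shifts the folds by too little to change any call, so it tests nothing here. An absolute log2 fold of at least 1 left 153 genes, 79 higher and 74 lower, because fewer genes reach it. The normal p of the deposited statistic gave 263, 132 higher and 131 lower: 213 of the 1036 passed, and 50 short RNA entries with a deposited p of at least 0.310 joined them, while 823 called genes did not pass.

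List medians kept their side of the central 95% with these exceptions, whose cause was not tested. The intermediate progenitor median was 0.085 with no pseudocount and 0.076 with no filter, at 5 FPKM and against unmatched lists, and no longer stood apart. At 5 FPKM the pyramidal median of 0.082 and the interneuron median of 0.057 no longer stood apart, while the thalamus median of -0.17 did, and the sex check median reversed to -0.17. The myelinating oligodendrocyte median was -0.12 with a pseudocount of 0.1, with none and at 5 FPKM, and no longer stood apart. The senescence median of 0.094 stood apart with no filter.

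Odds ratios changed side as follows. At a q of 0.01 the lower calls of the myelinating oligodendrocyte and thalamus lists had an odds ratio of 8.75 each, and against all tested genes the lower pyramidal calls passed at 8.19. With the normal p of the deposited statistic, the odds ratio was 12.6 for higher immature granule, 14.3 for higher pyramidal, 8.03 for lower oligodendrocyte precursor and 10.4 for lower thalamus calls, none past the threshold, and 0 for lower Cajal-Retzius, astrocyte and myelinating oligodendrocyte calls, where no member passed. Of 81 named genes called, 10 did not pass a q of 0.01 and 39 passed with the normal p of the statistic. No setting run on named genes could turn the sign of a fold.

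No paired analysis was possible because the table gives a single value per genotype. A count model and leaving out each replicate were not run for the same reason, and the unknown depth limits what the untested genes can show.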

Other observations

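The tests of families, of imprinted, choroid plexus epithelium, spermatid and second meningeal genes, of differences between lists, and of the explanations below were chosen after the called genes had been seen; the pyramidal, immature granule and choroid plexus lists themselves were chosen earlier. Of 22 gene families matched by symbol and tested in both directions (44 tests), collagens were over-represented among higher calls, with 14 of 26 measured members (odds ratio 30.6, adjusted p = 2.79e-12, Fisher's exact test). They included Col12a1, which went from 1.71 to 3.29 FPKM (log2 fold 0.95) in the authors' deposited table, and Col1a1, Col1a2 and Col3a1, which are also on the meningeal list. Potassium channel genes were over-represented among lower calls, with 18 of 66 (odds ratio 10.9, adjusted p = 1.13e-10, Fisher's exact test). In the same libraries the medians of mature granule neuron and astrocyte genes were -0.57 and -0.19 and that of meningeal genes was 0.50. The inward rectifier Kcnj4 went from 27.1 to 13.1 FPKM (log2 fold -1.04), while Kcnq5, the M-current subunit, went the other way from 6.55 to 13.6 FPKM (log2 fold 1.05) in the authors' deposited table. Copines passed among higher calls with 3 of 9 (adjusted p = 0.0417, Fisher's exact test). Zinc finger genes had few calls in either direction, 2 of 321 higher (odds ratio 0.156, adjusted p = 0.0127) and 4 lower (odds ratio 0.347, adjusted p = 0.114, Fisher's exact test). These tests were not matched on expression, and at a like fold calls were fewer among genes of 1 to 5 FPKM. With calls from the deposited statistic, 4 of the 14 collagens, Col12a1 and Col3a1 among them, Kcnj4 alone of the 18 lower potassium channels, Kcnq5, 2 of the 3 copines and 1 of the 2 higher zinc finger genes passed. No enrichment passed for semaphorins, Eph receptors and ephrins, protocadherins, cadherins, calcium channels, solute carriers, ADAMTS proteases, integrins, ribosomal proteins, synaptotagmins, laminins, kinesins, tubulins, complex I, the proteasome, dual specificity phosphatases or receptors named Gpr. The genes named in this part were chosen after their values were seen.

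Imprinted genes, expressed from a single parental allele, had 9 of 41 measured members higher and 2 lower (odds ratio 7.28 for higher calls, adjusted p = 0.000103 over 6 tests, Fisher's exact test). Nnat, the most abundant, went from 582 to 1116 FPKM (log2 fold 0.94), Plagl1 from 1.28 to 2.71 FPKM (log2 fold 1.08), Zim1 from 1.66 to 3.40 FPKM (log2 fold 1.03) and Ndn from 151 to 225 FPKM (log2 fold 0.58), while Rasgrf1 fell from 60.3 to 23.4 FPKM (log2 fold -1.36) in the authors' deposited table. The higher members also include Igf2 and Dcn of the meningeal list. The list's median was 0.087, at percentile 99.97 of matched random lists. Of the 9 higher genes, 6 passed with calls from the deposited statistic, Ndn and Igf2 not among them, and Rasgrf1 passed on the low side.

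The first pattern is the fall of mature granule neuron genes. A lower share of granule cells in the dissected tissue would raise the markers of every other type alike. The meningeal median instead exceeded the microglial and endothelial median by 0.53 on the log2 scale (permutation p = 2e-05, adjusted 3e-05, across genes). That p is the smallest these permutations can give. The oligodendrocyte precursor median lay below the microglial and endothelial median by -0.25 (permutation p = 2e-05). A lower granule share alone would leave these gaps unexplained. The lists were contrasted after their medians were seen and may move for reasons of their own. The gaps therefore cannot say how much of the granule fall such a share explains. More of the neighbouring pyramidal fields in the null dissections may contribute, with the pyramidal median at percentile 98.36, and so may delayed maturation of granule neurons, with the immature median at percentile 99.99. Each of these explanations needed the members of its list to move together. An explanation was left open where 3 or more members of its list were called each way, a limit set after the calls were seen. The pyramidal list had 5 higher and 3 lower calls, and the immature list 7 and 5. Neither explanation was decided, and a limit set this way counts neither for nor against them. An effect of the Jmjd3 deletion within granule neurons stays open and was not tested.

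The second pattern joins the rise of meningeal genes with the fall of Ttr. More meningeal tissue in the null dissections is a candidate explanation. A second meningeal list of 14 measured genes, written from genes not noticed among the calls, had a median of 0.20, at percentile 100 of matched random lists. Of its genes, 0 were called by Cuffdiff and 3 had an unadjusted Cuffdiff p under 0.05. Its members were picked after the calls were seen, so the 0 is no result and the median is limited as evidence. Its most abundant member, Mfap4, was at 30.2 FPKM in the control and 32.2 FPKM in the null in the authors' deposited table. Choroid plexus tissue in the control dissections may underlie Ttr, but 12 of the 18 genes of that list were lower and 6 higher, with 12 of them not tested, which leaves it open. Of 12 choroid plexus epithelium genes picked out of that list after their values were seen, 10 were lower and 2 higher, but their median was 0.353 FPKM in the control and 0.342 FPKM in the null, and that of all 18 was 0.353 and 0.383 FPKM, from the authors' deposited table. A change of these cells in the null animals was not tested.

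The third pattern is Prm1. A release of spermatid genes would raise others of its class, but 0 of 14 other spermatid genes reached 1 FPKM in the null with at least a 2-fold rise, and 12 of them, not tested by Cuffdiff, were below 1 FPKM in the null, 6 of these listed at 0, which argues against a release of the class to 1 FPKM or more. Reads of the Cre transgene are a candidate source of the log2 fold of 7.19, since some Cre constructs carry a protamine fragment, but the table does not say where in Prm1 the reads lie, so this stays open. A rise of Prm1 alone in the null was not tested.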
